A study of Mus musculus with 180 samples.

How the data were processed

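Bulk RNA was sequenced from 8 dissected brain regions of Srrm2 heterozygous mutant mice (HET) and wild-type littermates (WT) at 1 and 3 months of age, in 156 libraries. Single nuclei were sequenced from prefrontal cortex and striatum at 1 month, in 24 libraries. Per the labels' protocols, frozen brain was dissected in a cryostat and polyadenylated RNA was made into stranded libraries (TruSeq Stranded mRNA). Nuclei were released with a Triton-based buffer, enriched by flow sorting and prepared with the 10x Genomics v3 kit, also per the labels' protocols. The marker used for sorting is not given in the sources used here. The labels do not say whether replicates are separate animals or litters, and they give no sex, batch or date. They also do not say whether a replicate number denotes the same animal in each region.

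The bulk table holds expected counts per gene that the authors deposited without normalization. Per the submitters' processing notes they were made with RSEM 1.3.0 on GRCm38.p6, and the aligner is not given in the sources used here. Every deposited value was a whole number. The nuclei files hold deposited UMI counts per gene and nucleus. The processing notes name Cell Ranger 7.2.0 and 3.0.2 on mm10 without saying which made which file. Per the file headers and names, the prefrontal cortex matrices are Cell Ranger's filtered barcodes, and those of the striatum are filtered output of CellBender, whose version and settings are not given in the sources used here. The prefrontal cortex and striatum were therefore never compared with each other. Of 34759 bulk gene identifiers, 34656 (99.7%) matched a gene of GENCODE release M21 on GRCm38, from which positions, lengths and GC content were taken.

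For each region and age, HET libraries were compared with WT libraries by edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, genotype as the only term). Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Standard errors are the size of the log2 difference divided by the root of F. Changes common to the regions were tested with limma 3.58.1 (eBayes with trend) on each replicate number's mean log2 CPM over regions, with a prior count of 2. At 1 month this mean covered 8 regions. At 3 months it covered 6, since prefrontal cortex and substantia nigra lack libraries. These means assume that the numbers of 1 genotype and age may be averaged across regions, and their n, standard errors and splits rest on that. If libraries of 1 animal carried different numbers, the means would not be independent. The dependence of the genotype difference on age was tested with limma on the means over the 6 regions complete at both ages, and with edgeR in each region. Preset gene lists were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 measured genes. The 20 lists were myelinating oligodendrocyte, newly formed oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, vascular, choroid plexus, cortical excitatory neuron, GABAergic interneuron, striatal projection neuron, dopamine neuron, cerebellar neuron, immediate-early response, splicing factor and nuclear speckle, postsynaptic density, presynaptic release, cytosolic ribosomal protein, oxidative phosphorylation, cholesterol biosynthesis and exome-wide schizophrenia risk.

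Nuclei with at least 500 genes and at most 5% mitochondrial counts were kept. In each library the nuclei with the highest Scrublet scores were removed as doublets, at 0.8% per 1000 nuclei, which removed 6681 nuclei in prefrontal cortex and 5503 in striatum. Counts were scaled to 10000 per nucleus and log-transformed (scanpy 1.11.5). Clusters came from 2000 variable genes without Srrm2 and mitochondrial genes, 30 principal components, 15 neighbours, a shared-neighbour graph and Leiden modularity clustering at resolution 1 (igraph 0.11.9). A cluster took a class name from preset markers if at least 3 of them, making up a share of 0.5 of the class's markers or numbering at least 5, were detected in a share of at least 0.1 of its nuclei and at least 2-fold above the median cluster. The class with the highest mean log2 fold over its markers was taken. A cluster stayed unnamed if a class of another lineage also met the marker rule, with a mean log2 fold of at least 0.5 of that class's highest in any cluster. It also stayed unnamed if another class had more markers among its top 10 genes or if choroid plexus genes led there. The same held if a single library held more than a share of 0.5 of it, or if its UMI counts were low with no marker among those genes. These naming thresholds were set after the data were seen, and they left unnamed 2.14% ± 2.50 (SD, n = 6) of nuclei in WT and 1.68% ± 0.67 (n = 6) in HET prefrontal cortex. The unnamed share was 2.80% ± 1.50 (n = 6) in WT and 1.98% ± 1.15 (n = 6) in HET striatum. Counts were summed per library and class where at least 20 nuclei were present, and classes with at least 4 such libraries per genotype were tested with edgeR as above. Ependymal-like, progenitor-like and fibroblast-like nuclei of the striatum were too few for that test. Class shares were compared by exact two-sided permutation tests over all 924 splits of 12 libraries, on log2 odds with 0.5 added to both counts.

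Tests, gene lists, markers and the rule for naming genes were fixed before the data were examined. Named are Srrm2 in each comparison, Agap3 as a summary, the 10 genes higher and 10 lower with the smallest p in the mean over regions at each age, and 2 and 2 in each region and each class. Srrm2, predicted or clone genes and mitochondrial genes are passed over, and part of the genes with the largest p is not printed. Genes named outside this rule are said to be so. The alternatives chosen then were DESeq2 1.42.0, RLE factors, no filter on low counts, a prior count of 0.5, the replicate number as a block, an estimated correlation for the lists, other region sets, resolution 0.5, no doublet removal, other denominators for shares and leaving out each bulk library in turn. Added after the data were seen were a fit of 1-month striatum with the mean log2 CPM of the preset cortical excitatory neuron genes as a covariate, and a 1-month mean over the 7 regions other than striatum. A correction for GC content and gene length was added after a trend with GC content had been seen. It fits, per library, a spline of each gene's deviation on GC content (5 df) and log2 length (4 df), and enters edgeR as an offset. No pair of replicates among 305 pairs in 32 groups was a copy of another, as the lowest chi-square per degree of freedom was 8.87.

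The procedures were tested on simulated counts made from the real means and depths. For 1-month prefrontal cortex (18615 genes), edgeR recovered 28.1% of genes changed 1.25-fold, 61.5% of those changed 1.5-fold and 81.0% of those changed 2-fold, with 5 unchanged genes called. For 3-month substantia nigra (19120 genes), which has the fewest libraries, these shares were 1.52%, 20.0% and 56.7%, with 3 unchanged genes called. DESeq2 called 26 unchanged genes in the former setting and 34 in the latter. With a simulated GC trend in 1-month prefrontal cortex (18579 genes), 4432 unchanged genes were called without the correction and 7 with it. The simulated trend was linear in the GC values that the correction uses and equal in all HET libraries. A bias of another form was not simulated. For the 1-month mean over 8 regions (16339 genes), limma recovered 79.1% of genes changed 1.25-fold. The regions were simulated independently, so effects shared by the libraries of a replicate number were left out of that share. In summed nuclei, 78.8% of genes changed 1.5-fold were recovered in prefrontal excitatory neurons (19266 genes) and 10.9% in striatal oligodendrocytes (9998 genes).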

Results

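Srrm2 encodes a large protein of nuclear speckles, the compartments that hold splicing factors, and the study asks what the loss of a single copy does to gene expression across the mouse brain. Bulk libraries came from prefrontal cortex, somatosensory cortex, hippocampus, striatum, thalamus, substantia nigra, cerebellar cortex and cerebellar vermis. At 1 month each of the 8 regions had 5 WT and 5 HET libraries. At 3 months each region had 5 and 5, except prefrontal cortex (4 WT, 5 HET) and substantia nigra (4 WT, 3 HET). Total counts per library ranged from 21478639 to 94142524. The median was 43628545 for WT and 45318231 for HET at 1 month, and 53962662 and 56828094 at 3 months. Nuclei came from 6 WT and 6 HET libraries each in prefrontal cortex and striatum at 1 month. After filtering, 92225 nuclei remained in prefrontal cortex (6462 to 10240 per library) and 82526 in striatum (4998 to 8455 per library). The median UMI count per nucleus ranged from 5008 to 7530 across prefrontal cortex libraries and from 5458 to 8690 across striatum libraries.

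Srrm2 (ENSMUSG00000039218.17, GRCm38 chromosome 17, 23790532 to 23824741) was measured to ask how far its RNA fell in the mutants. In 1-month prefrontal cortex it fell from 640 ± 29.1 CPM in WT to 308 ± 35.8 in HET (SD, n = 5 each), 48.1% of the WT level. At 3 months it fell from 715 ± 43.3 CPM (n = 4) to 344 ± 18.2 (n = 5), 48.2% of the WT level. In 1-month cerebellar cortex the fall was smaller, from 496 ± 77.7 to 396 ± 39.6 CPM (n = 5 each), and in 3-month cerebellar cortex the values were 495 ± 114 and 428 ± 22.5 CPM (n = 5 each). The log2 difference was negative in 16 of 16 comparisons, from -1.05 in prefrontal cortex at both ages to -0.21 in 3-month cerebellar cortex. edgeR called Srrm2 in 7 of the 16, which were prefrontal cortex and substantia nigra at both ages and somatosensory cortex, striatum and thalamus at 1 month. DESeq2 called it in 12. With the GC and length correction edgeR called it in 8, without 3-month substantia nigra (-0.62, adjusted p 0.103) but with 1-month cerebellar cortex (-0.42, 0.0451) and 3-month thalamus (-0.57, 0.0482). The call in 1-month striatum was lost with the cortical markers as a covariate (-0.75 ± 0.17, 0.0817). The mean fall over both cerebellar regions was smaller than that over the other 6 regions at 1 month (-0.31 against -0.80, a difference of 0.50) and than that over 4 other regions at 3 months (-0.19 against -0.67, a difference of 0.48), where prefrontal cortex and substantia nigra, which lack libraries, were left out. In both cases the two-sided exact permutation p was 0.00794 over all splits of 5 WT and 5 HET replicate numbers, and this test was chosen after the values were seen. The change with age was not past the threshold in any region (adjusted p of at least 0.695). Leaving out HET 1, WT 1, WT 2, WT 3 or WT 4 ended the call in 3-month substantia nigra (log2 -0.69 to -0.63 without them). Leaving out WT 1 or WT 4 added a call in 1-month cerebellar cortex (-0.39 and -0.38). A call was added in 3-month thalamus without HET 5 or WT 1 (-0.67 to -0.63), and in 3-month somatosensory cortex without WT 1 (-0.83).

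**Figure D1:**
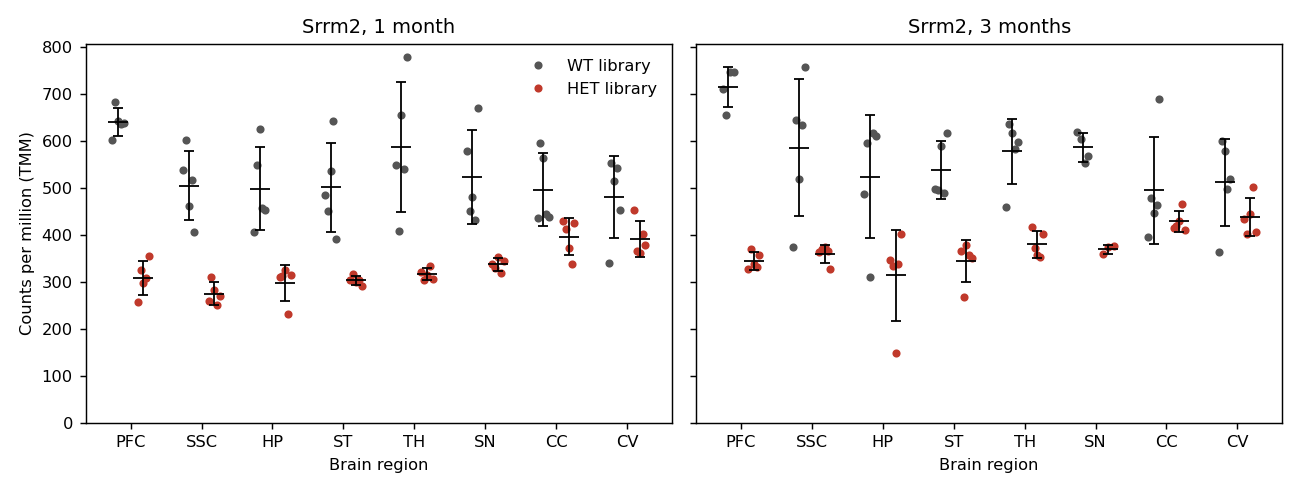
Srrm2 in CPM (vertical axis) in each bulk library by region (horizontal axis) and genotype, at 1 month (left) and 3 months (right), with mean and SD. HET means lie at 48.1% of WT in 1-month prefrontal cortex and closer to WT in both cerebellar regions.

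The series title names Agap3, whose splicing gene-level counts cannot separate. Summed over isoforms, Agap3 was called in 0 of 16 bulk comparisons by edgeR and in 1 by DESeq2, with 3 at an unadjusted p under 0.05. Its log2 differences ranged from -0.20 to 0.16, with a smallest adjusted p of 0.0868. Leaving out HET 5 gave 1 call of Agap3. In nuclei, edgeR called Agap3 in 0 of 8 classes of prefrontal cortex (-0.31 to 0.25, smallest adjusted p 0.887) and 0 of 10 of striatum (-0.38 to 0.04, 0.984). DESeq2 also called it in 0 classes, and 1 of these tests in nuclei, in prefrontal cortex, had an unadjusted p under 0.05.

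Each region was then tested for other genes that differed between HET and WT at 1 month, the age at which edgeR called more genes in each region. In striatum, Kctd12 rose from 79.6 ± 8.59 to 140 ± 5.38 CPM (SD, n = 5 each; log2 0.81 ± 0.07 SE, adjusted p 0.000411). Mctp1 rose in the same region (0.67 ± 0.06) and Arhgef25 fell (-0.91 ± 0.09), both with the same adjusted p, and all 3 calls held without any 1 library. In the same libraries all 12 cortical excitatory neuron genes of the preset list were lower in HET (median -1.15, 10 of them called, among them Fezf2 at -1.49 ± 0.31) and all 17 striatal projection neuron genes were higher (0.40, 14 called, among them Isl1 at 0.94 ± 0.10). Changes within striatal cells were therefore not separated from a difference in the dissected tissue. With the mean of the cortical markers as a covariate, chosen after the data were seen, Kctd12 (0.74 ± 0.10, 0.0442) and Mctp1 (0.62 ± 0.09, 0.0481) were still called and Arhgef25 was not (-0.69 ± 0.11, 0.0542). In cerebellar cortex, Marcks rose from 130 ± 16.3 to 268 ± 11.8 CPM (n = 5 each; 1.05 ± 0.08, 0.000215). In cerebellar vermis, Marcks rose by 0.76 ± 0.10 (0.0169) and Cyp2d22 fell by 0.54 ± 0.08 (0.0247). The call of Marcks there was lost without HET 2, HET 3, HET 4 or WT 5 (0.72 to 0.77), and that of Cyp2d22 without these or HET 5 (-0.57 to -0.52). In prefrontal cortex, Tmx1 rose (0.44 ± 0.05) and Kifc2 fell (-0.34 ± 0.04), both with an adjusted p of 0.00726. In somatosensory cortex, Vma21 rose (0.48 ± 0.05, 0.0013) and the pseudogene Morf4l1-ps1 fell (-1.26 ± 0.09, 7.27e-05). Morf4l1-ps1 also fell in thalamus (-1.39 ± 0.22, 0.00856) and cerebellar cortex (-1.59 ± 0.09, 8.27e-06), while its parent gene Morf4l1 rose in thalamus (0.56 ± 0.05, 0.000841). In substantia nigra, Ptpn4 (0.81 ± 0.08) and Trim59 (1.15 ± 0.11) rose, both with an adjusted p of 0.00136, and the GC and length correction reduced the rise of Ptpn4 to 0.28. The pseudogene Apoo-ps had no count in HET thalamus and was at least 276-fold lower there than in WT (WT 3.73 CPM, limit of 3 counts over all HET libraries 0.0135 CPM), and at least 155-fold lower in substantia nigra. In hippocampus the only gene called by edgeR, among 1621 at an unadjusted p under 0.05 and 187 called by DESeq2, was Gt(ROSA)26Sor (1.27 ± 0.14, 0.0152). That call was lost with the GC and length correction (adjusted p 0.0634) and without HET 5, WT 1, WT 2, WT 3 or WT 4 (1.22 to 1.33), and 7 of 30 splits of the libraries there called at least 1 gene. Reads of the pseudogenes, of Morf4l1 and of other near-identical copies cannot be assigned with certainty, so these values are uncertain.

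The number of genes called by edgeR at 1 month differed widely between regions, a difference that was not itself tested. In striatum 3060 of 17663 genes were called (1556 higher, 1504 lower), and 2411 with the GC and length correction (1175 higher, 1236 lower), of which 1882 were shared. With the mean of the cortical markers as a covariate, 10 genes were called there (6 higher, 4 lower; 2611 at an unadjusted p under 0.05). That covariate correlated with genotype (Pearson's r -0.767), so part of the loss is a loss of power. Of 3016 called genes also measured in somatosensory cortex, 79.5% differed in the direction away from WT cortex, against 58.7% of 14139 genes not called. In substantia nigra the count was 2966 of 18085 (1577 higher, 1389 lower), and 243 with the correction (91 higher, 152 lower). The count was 1550 to 1959 without HET 2, HET 3, WT 2 or WT 3. In cerebellar cortex 2038 of 18379 genes were called (1268 higher, 770 lower), and 485 with the correction (205 higher, 280 lower). The count was 422 to 1269 without HET 1, HET 2, HET 4, HET 5, WT 2 or WT 5. Prefrontal cortex had 938 of 18854 (599 higher, 339 lower) and 31 with the correction (12 higher, 19 lower), and 216 to 507 without HET 1, HET 2, HET 4, WT 1, WT 2 or WT 4. Thalamus had 472 of 18201 (413 higher, 59 lower) and 96 with the correction (54 higher, 42 lower), and 215 to 310 without HET 2, HET 3, HET 4, WT 2 or WT 4. Somatosensory cortex had 300 of 18052 (250 higher, 50 lower) and 179 with the correction (134 higher, 45 lower), and 120 to 198 without HET 1, HET 3, HET 5, WT 1, WT 2 or WT 5. Cerebellar vermis had 144 of 18374 (104 higher, 40 lower) and 18 with the correction (10 higher, 8 lower). Its count was 2 to 23 without HET 2, HET 3, HET 4, HET 5, WT 2, WT 3, WT 4 or WT 5, and 604 without HET 1. In hippocampus the single call of 18306 genes became 4 without HET 4 and 8 without WT 5, and 0 (DESeq2 187 with all libraries) without HET 5, WT 1, WT 2, WT 3 or WT 4. Log2 differences in 1-month prefrontal cortex followed the genes' GC content with a Spearman's rho of -0.490 across genes, which are not independent replicates, and in substantia nigra with -0.583.

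**Figure D2:**
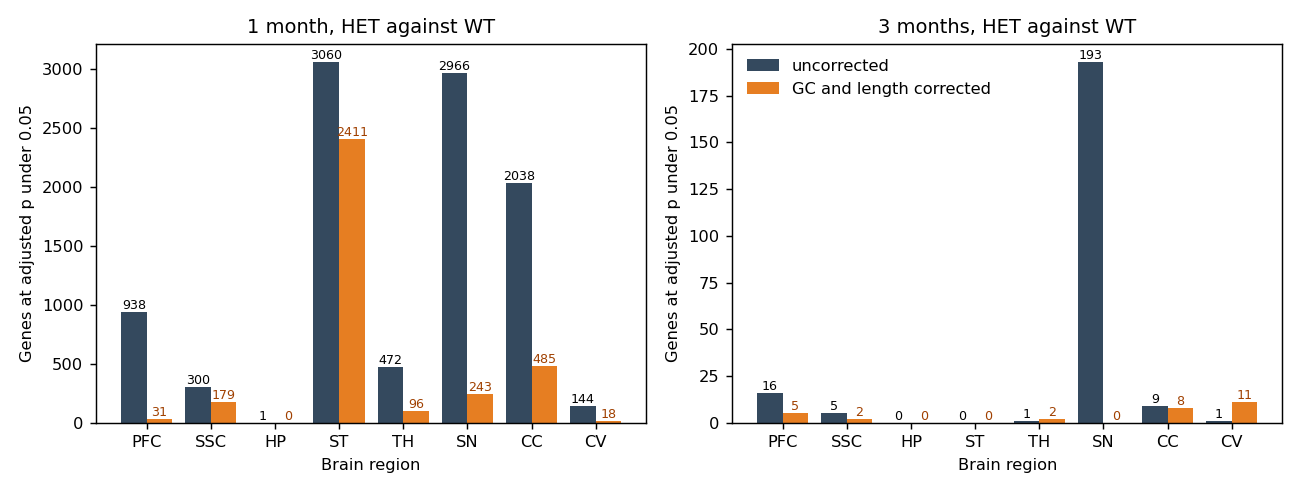
Number of genes called by edgeR (vertical axis) in each bulk region (horizontal axis) at 1 month (left) and 3 months (right), without and with the GC and length correction (paired bars). Striatum had 3060 and 2411 at 1 month and prefrontal cortex 938 and 31, and the highest count at 3 months was 193, in substantia nigra.

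At 3 months the same comparison asked which differences were present in adult tissue. In prefrontal cortex, Pxn fell from 34.9 ± 1.65 CPM (n = 4) to 19.3 ± 1.34 (n = 5; log2 -0.85 ± 0.06 SE, adjusted p 0.000361) and Ldhd fell by 0.54 ± 0.06 (0.00509). Both were among 16 of 19126 genes called there (5 higher, 11 lower), and both calls held without any 1 library. That count was 5 to 10 without HET 1, HET 2, HET 3, HET 4, WT 2, WT 3, WT 4 or WT 5, and 117 without HET 5. In cerebellar cortex, Mdfi fell from 14.0 ± 1.63 to 6.99 ± 0.70 CPM (n = 5 each) and Ece2 by 0.57 ± 0.06, both with an adjusted p of 0.00411, among 9 of 18620 genes called. The count was 2 to 4 without HET 1, HET 2, HET 3, HET 4, WT 1, WT 3 or WT 4, and 36 without HET 5. Ece2 was also the 1 gene of 18673 called in cerebellar vermis (-0.54 ± 0.06, 0.0145). Its call was lost without HET 1, HET 2, HET 3, WT 4 or WT 5 (-0.54 to -0.51), and 3 to 34 genes were called without HET 5, WT 1 or WT 3. In substantia nigra, Plekhg2 (-1.12 ± 0.11) and Cerox1 (-0.73 ± 0.08) fell (adjusted p 0.0314), among 193 of 19506 genes called (44 higher, 149 lower). That balance turned with the replicate number as a block (186 higher, 131 lower), but the block fit kept only the 2 replicate numbers found in both genotypes. Replicate numbers are those of the sample descriptions, while the titles of these libraries number HET 3 as replicate 2 and HET 5 as replicate 3. The calls of Plekhg2 and Cerox1 were lost with the GC and length correction, which left 0 genes called by edgeR there (4122 at an unadjusted p under 0.05 and 1674 by DESeq2, both without it). Leaving out HET 1, HET 5, WT 1, WT 2, WT 3 or WT 4 gave 0 to 16 genes, and leaving out HET 3 gave 415. In somatosensory cortex 5 of 18524 genes were called, which were Vsig2 (0.57 ± 0.06, 0.0172), Ldhd (-0.57 ± 0.07, 0.0226), Gpt (-0.52 ± 0.07), Hrh3 and Gfra4, the last 2 named after their values were seen. With the GC and length correction 2 genes were called there and Gpt was not (0.164). The count there was 0 to 2 without HET 1, HET 2, HET 3, HET 4, WT 2, WT 3, WT 4 or WT 5, and the calls of Vsig2 and Ldhd held in 3 of the 10 fits that leave out 1 library, that of Gpt in 0. In thalamus the predicted gene Gm16233, named after its value was seen, was the 1 gene of 18674 called (1.87 ± 0.19, 0.00919). The count was 4 to 31 without HET 2, HET 5 or WT 1, and 0 without WT 3 (1965 at an unadjusted p under 0.05 and 99 by DESeq2 with all libraries). In hippocampus edgeR called 0 of 18872 genes (768 at an unadjusted p under 0.05, 15 by DESeq2) and in striatum 0 of 18477 (1255 and 31), and these 0 counts held without any 1 library. Other splits of the same libraries called up to 56 genes in prefrontal cortex, 954 in somatosensory cortex, 1064 in striatum, 17 in thalamus and 29 in cerebellar vermis, and no more than 1 in substantia nigra and 0 in cerebellar cortex.

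The mean over regions asked which differences were common to the brain. At 1 month Ece2 (GRCm38 chromosome 16, 20629828 to 20646485) fell by 0.58 ± 0.04 (SE; adjusted p 6.39e-06, n = 5 each), and at 3 months by 0.50 ± 0.04 (0.000295). Cyp2d22 fell at both ages (-0.46 ± 0.04, 1.5e-05 and -0.39 ± 0.07, 0.0265), as did Coasy (-0.34 ± 0.03, 1.54e-05 and -0.25 ± 0.03, 0.00771). With the GC and length correction the 3-month call of Cyp2d22 was lost (adjusted p 0.0545). At 1 month Cadm2 rose by 0.57 ± 0.03 (1.76e-06), or by 0.20 ± 0.03 (0.000884) with the GC and length correction. Eif1ax rose by 0.35 ± 0.02 (1.09e-06) and Pcmtd1 by 0.41 ± 0.02 (1.38e-06), or by 0.13 and 0.16 with the correction. The call of Tmx3 (0.39 ± 0.02, 1.97e-06) was lost with the correction, under which its difference was -0.01 ± 0.03 (0.876). Zfp968 (1.68 ± 0.09, 1.09e-06) and Gt(ROSA)26Sor (1.23 ± 0.07, 1.97e-06) rose, and the pseudogene Zxda fell (-2.98 ± 0.19, 2.11e-06), all 3 being uncertain where near-identical copies share reads. Srrm2 fell by 0.68 ± 0.04 (1.09e-06) at 1 month and by 0.51 ± 0.09 (0.0253) at 3 months. The 3-month call of Srrm2 was lost without HET 1, HET 2, HET 3, HET 4, WT 2, WT 3 or WT 4 (-0.53 to -0.48). At 3 months Casp1 rose by 0.62 ± 0.07 (0.00247) and Cabp4 by 0.87 ± 0.13 (0.012), while Prr22 (-1.35 ± 0.11, 0.000273), Prpsap1 (-0.31 ± 0.03, 0.000769) and Haghl (-0.36 ± 0.04, 0.000794) fell. Casp1 (0.44 ± 0.10), Cabp4 (0.63 ± 0.14), Prpsap1 (-0.32 ± 0.04) and Haghl (-0.30 ± 0.05) were also called at 1 month, while Prr22 was not tested in that mean. Levels of Casp1, Cabp4 and Prr22 were low (0.09, -1.03 and -0.48 log2 CPM in 3-month WT). Haghl lies within 10 Mb of Srrm2 on chromosome 17. Lrrc26 rose by 1.12 ± 0.12 (0.00207) and Grin1, named after its value was seen, fell by 0.22 ± 0.03 (0.0152), a call lost with the GC and length correction (-0.14, 0.117). Both genes were also called at 1 month (1.12 ± 0.09 and -0.23 ± 0.03), and the level of Lrrc26 was low (-0.95 log2 CPM in 3-month WT). Lrrc26 ends at position 25291180 of chromosome 2 and Grin1 starts at 25291181, so reads of the 2 genes are hard to assign and both values are uncertain.

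In the 1-month mean over 8 regions, limma called 6271 of 16339 genes (3081 higher, 3190 lower), with a median size of 0.17 on the log2 scale. With the GC and length correction it called 2583 (1256 higher, 1327 lower), of which 1778 were called both ways in the same direction. In the 3-month mean over 6 regions, 91 of 16934 genes were called (27 higher, 64 lower), and 55 with the correction (24 higher, 31 lower). The counts depend on the regions and the model: on the same 6 regions the 1-month count was 4088, and at 3 months it was 848 over all 8 regions (244 higher, 604 lower) and 4 with the replicate number as a block. That 3-month count was 26 to 60 without HET 1, HET 2, HET 3, HET 4, WT 2, WT 3 or WT 4, and 363 without HET 5. Among 16242 genes tested at both ages, 15 of the 24 genes called higher at 3 months were also called higher at 1 month (4.53 expected, Fisher's exact p 3.06e-06). Of the 60 called lower at 3 months, 59 were also called lower at 1 month (11.8 expected, Fisher's exact p 5.88e-41), and 0 genes were called in opposite directions. Genes are not independent replicates, so these p-values are too small. The 74 genes called at both ages became 19 to 48 without HET 1, HET 2, HET 3, HET 4, WT 1, WT 2, WT 3 or WT 4, and 226 without HET 5, each replicate number left out at both ages. Across genes the log2 differences of the ages correlated with a Pearson's r of 0.404 and a Spearman's rho of 0.451, or 0.333 and 0.314 with the correction.

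Whether a difference depended on age was tested on the mean over 6 regions. Morf4l1-ps1 (6.52 ± 0.19 log2 CPM in 1-month WT, SD, n = 5 in each group) was at 5.20 ± 0.15 in 1-month HET, against 6.74 ± 0.21 and 6.90 ± 0.07 in WT and HET at 3 months. Its difference changed with age by 1.47 ± 0.13 (SE, adjusted p 4.13e-06). Zxda was at 1.95 and -0.72 in WT and HET at 1 month and at 2.15 and 2.11 at 3 months, while its near-identical gene Zxdb was at 3.55 and 4.21, then 3.64 and 3.6. Gt(ROSA)26Sor was at 1.2 and 2.49 at 1 month, and at 1.15 and 1.23 at 3 months (change with age -1.21 ± 0.12, 1.49e-05). Mitochondrial mt-Atp8 was at 6.48 ± 0.27 and 8.90 ± 0.14 at 1 month, and at 6.13 ± 0.29 and 5.88 ± 0.26 at 3 months. The overlapping gene mt-Atp6 was at 6.84 and 6.99, then 6.80 and 6.74. Cadm2 changed with age by -0.64 ± 0.07 (4.38e-05), or by -0.33 with the GC and length correction. These genes were named after their values were seen, and those with near-identical copies or overlapping genes are uncertain. Of 16339 genes, 725 were called (86 with a positive and 639 with a negative change), and 420 with the correction (158 positive, 262 negative). The count was 454 to 477 without WT 2, WT 3 or WT 4 of 3 months, and 1375 without WT 1 of 3 months, and another split of the same libraries gave 1279. Apoo-ps had no count in any of 40 HET libraries of 1 month, and had counts in 16 of 40 WT libraries of 1 month and in 27 of 38 libraries of each genotype at 3 months. The labels give no batch, so dependence on age is not separated from any difference in handling of the 1-month HET libraries.

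**Figure D3:**
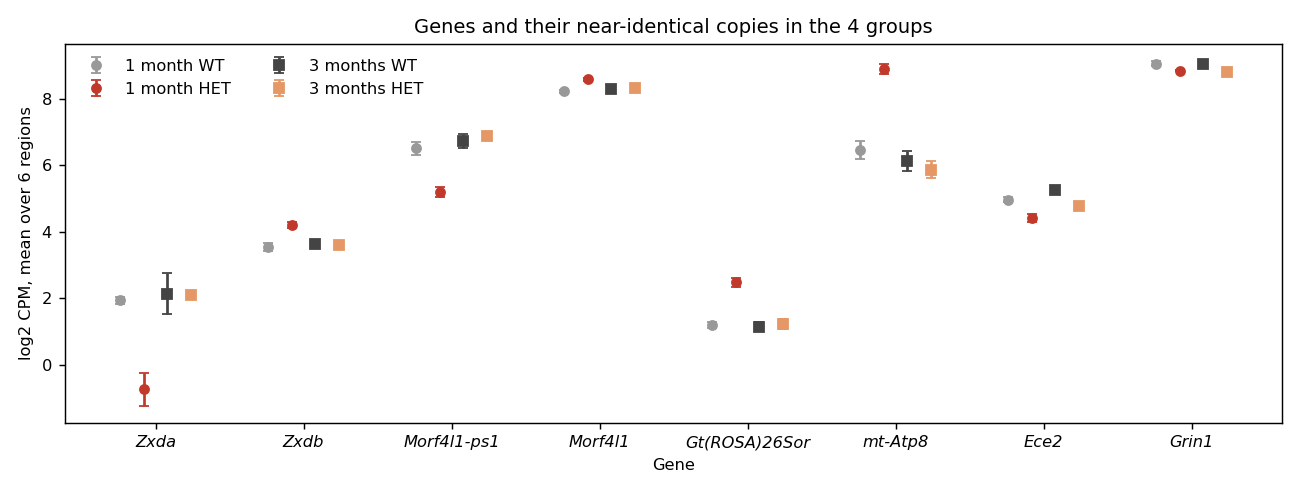
Log2 CPM averaged over 6 regions (vertical axis, mean and SD of 5 replicate numbers) of 8 genes in WT and HET at 1 and 3 months (horizontal axis). Zxda, Morf4l1-ps1, Gt(ROSA)26Sor and mt-Atp8 differ from the other 3 groups in 1-month HET, as for mt-Atp8 with 8.90 against 5.88 to 6.48, while Ece2 and Grin1 are lower in HET at both ages.

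Region by region, edgeR called age-dependent differences in 195 genes in substantia nigra (111 positive, 84 negative), 109 in striatum (14 positive, 95 negative), where cortical markers also differed between the 1-month genotypes, 17 in somatosensory cortex (4 positive, 13 negative) and 13 in cerebellar cortex (5 positive, 8 negative). In cerebellar vermis it called 4, which were mt-Atp8 (-2.88 ± 0.36 SE), Marcks (-0.68 ± 0.11), Gm10241 (2.06 ± 0.31) and Gm27517, and in thalamus 1, Gm37701, all named after their values were seen. In prefrontal cortex it called 0 of 19971 genes (584 at an unadjusted p under 0.05) and in hippocampus 0 of 19509 (880). No other tool was run for this test, but RLE factors also gave 0 in both.

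The preset lists asked whether markers of a cell type or members of a process moved together. The 27 myelinating oligodendrocyte genes were lower in 3-month substantia nigra, with a median log2 difference of -0.42 and 27 of 27 below 0 (camera adjusted p 5.51e-13). With a correlation estimated from the libraries, however, neither this list nor any other was called in any comparison, and the adjusted p of this list was at least 0.984. Their mean level was 8.17 ± 0.08 log2 CPM in WT (SD, n = 4) and 7.70 ± 0.15 in HET (n = 3), with an exact two-sided permutation p of 0.0286, the smallest possible there. Among them Ppp1r14a fell by 0.87 ± 0.11 (SE, adjusted p 0.0315) and Fa2h by 0.79 ± 0.12 (0.042). In all 8 members were called over all genes, and 23 adjusted over the list alone, but the GC and length correction left no gene called there, so none of these 8 calls held, while camera still called the list (8.32e-17). The same list was lower in 3-month cerebellar vermis (-0.22, 26 of 27, 3.02e-08), with 0 members called by edgeR over all genes and 1 adjusted over the list alone (exact permutation p 0.0952). In 3-month striatum it was lower (-0.19, 26 of 27, 2.68e-07, exact permutation p 0.143), in 3-month prefrontal cortex (-0.23, 24 of 27, 0.0214) and in 3-month cerebellar cortex (-0.10, 23 of 27, 0.00925). At 1 month it was lower in somatosensory cortex (-0.14, 25 of 27, 0.0177) and prefrontal cortex (-0.17, 21 of 27, 0.0478), and higher in cerebellar vermis (0.14, 0.0214). Whether these differences depended on region or age was not tested. The call in 1-month prefrontal cortex was lost with the GC and length correction (0.0942) and with RLE factors (0.0587).

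Over the 20 lists and 16 comparisons, camera called 80 of 318 tests (24 higher, 56 lower), 69 with the GC and length correction and 0 with an estimated correlation (smallest adjusted p 0.984). Each of 100 splits of the same libraries, the real one included, gave at least as many calls (at most 132), so the number of calls is not beyond chance. Cytosolic ribosomal protein genes were higher in 4 comparisons and lower in 10, and in 1-month cerebellar cortex 52 of 54 were lower (median -0.21, adjusted p 2.9e-11). There 12 were called over all genes and 30 adjusted over the list alone. Oxidative phosphorylation genes were higher in 3 and lower in 7, and in 1-month cerebellar cortex 64 of 65 were lower (-0.25, 4.96e-16), with 25 called and 52 adjusted over the list alone. Splicing factor and nuclear speckle genes were higher in 6 and lower in 1, and in 1-month cerebellar cortex their median was 0.37 (0.00101), with Tra2b at 0.47 ± 0.09 and Luc7l2 at 0.78 ± 0.16. Postsynaptic density genes were lower in 7 comparisons and presynaptic release genes in 3. With the GC and length correction the postsynaptic genes were higher in 1 and lower in 3, and the presynaptic genes higher in 2 and lower in 1. Striatal projection neuron genes were higher in 1 and lower in 4, GABAergic interneuron genes higher in 2 and lower in 1, cerebellar neuron genes higher in 3 and lower in 1, and cortical excitatory neuron genes lower in 2. The striatal projection neuron genes were higher, and the cortical excitatory neuron genes lowest (median -1.15), in 1-month striatum, the region with the most genes called. Vascular genes were lower in 4, astrocyte genes in 2, microglia genes in 1 and newly formed oligodendrocyte genes in 1, while oligodendrocyte precursor genes were higher in 1. Choroid plexus genes were higher in 1 and lower in 1, immediate-early response genes lower in 2, cholesterol biosynthesis genes lower in 1, and exome-wide schizophrenia risk genes higher in 2 and lower in 1. With the GC and length correction immediate-early response genes were higher in 2 and lower in 1, and the schizophrenia risk genes were called in no comparison. Dopamine neuron genes were called by camera in no comparison. Summed over all tests, 131 members were called higher and 189 lower over all genes, and 265 and 369 adjusted over the list alone.

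In nuclei, Srrm2 was measured in each class to ask where its RNA fell. In prefrontal excitatory neurons it fell from 708 ± 40.6 to 205 ± 10.3 CPM (SD, n = 6 each; log2 -1.79 ± 0.05 SE, adjusted p 1.24e-11). In striatum it fell in D1 projection neurons from 624 to 216 CPM (-1.53, n = 6 each), in cholinergic interneurons from 1241 to 349 CPM (-1.83 ± 0.12, n = 6 and 5) and in oligodendrocytes from 459 to 229 CPM (-1.01, n = 6 each). It was called in 9 of 10 classes of prefrontal cortex (-1.79 to -0.68) and in 10 of 12 of striatum (-1.83 to -0.27). The exceptions were mural cells of prefrontal cortex (-0.69, adjusted p 0.0947), and endothelial (-0.27, 1.00) and mural cells (-0.69, 0.606) of striatum. All 6 HET libraries lay below the lowest WT library in mural cells of prefrontal cortex, 2 of 6 in those of striatum and 3 of 6 in striatal endothelial cells. Mural sums held 76009 to 124844 UMIs per library in prefrontal cortex and 65898 to 144391 in striatum, so a fall there could be missed. The call in striatal microglia was lost with the GC and length correction (-0.68, 0.421).

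Other genes were tested in the same classes. In prefrontal excitatory neurons, Pxn fell from 10.8 to 5.86 CPM (log2 -0.88 ± 0.08 SE, adjusted p 0.000215, n = 6 each) and Kctd17 fell by 0.42 (0.00852), while Ap1g2 rose by 0.78 ± 0.09 (0.00119) and Jph4 by 0.32 (0.0159). In D1 striatal projection neurons, Mdk fell from 127 ± 12.2 to 42.9 ± 4.09 CPM (-1.57 ± 0.08, 3.1e-07, n = 6 each). Zbtb4 rose in prefrontal interneurons (0.54, 0.0145), Rpl36al fell in striatal astrocytes (-2.24, 0.0441), and Grin2a (3.27, 0.0106) and Chsy3 (1.63, 0.0227) rose in striatal cholinergic interneurons (n = 6 and 5). Grm7 (-1.5, 0.0162) and Chsy3 (-0.93, 0.0359) fell in newly formed oligodendrocytes of prefrontal cortex by edgeR but were not called by DESeq2 (0.860 and 0.839). Without doublet removal the calls of Grin2a (1.75, 0.239) and Chsy3 (1.07) in cholinergic interneurons, of Rpl36al (0.0623), and of Grm7 (-0.63) and Chsy3 (-0.43, both 0.902) in newly formed oligodendrocytes were lost, and that of Rpl36al also without the low-count filter (0.0675). With the replicate number as a block the calls of Rpl36al (adjusted p 0.281) and Jph4 (0.0526) were lost. In all, 24 of 90115 tests were called in prefrontal cortex (8 higher, 16 lower), 15 of them in genes other than Srrm2. In striatum 15 of 99329 were called (3 higher, 12 lower), 5 of them in genes other than Srrm2. At an unadjusted p under 0.05 the counts were 4810 and 3704. In each region 2 of 30 splits, the real one included, called as many genes (at most 73 in prefrontal cortex and 21 in striatum).

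Class shares asked whether cell types were fewer in the mutants. Oligodendrocytes made up 16.9% ± 1.37 of striatal nuclei in WT and 14.2% ± 1.83 in HET (SD, n = 6 each), lower than the WT mean in 6 of 6 HET libraries. HET 6, at 10.5%, lay apart from the other HET libraries (14.2% to 15.3%). The log2 odds differed by -0.31 (exact two-sided permutation p 0.00649, adjusted over 15 classes 0.0758), which is not past the threshold. In prefrontal cortex the oligodendrocyte share was 2.54% ± 0.74 in WT and 1.86% ± 0.47 in HET (n = 6 each; -0.45, exact permutation p 0.108, adjusted 0.541). D1 projection neurons made up 30.8% ± 1.33 of striatal nuclei in WT and 32.9% ± 1.04 in HET (n = 6 each, exact permutation p 0.0152). D2 projection neurons made up 24% ± 1.01 and 26.3% ± 1.58 (p 0.0108 by the same test). Neither was past the threshold (adjusted p 0.0758 for both), and within neurons the D1 difference reversed sign. Astrocytes in prefrontal cortex made up 10.8% in WT and 12.0% in HET (exact permutation p 0.0498, adjusted 0.498, n = 6 each). The exact test called 0 classes in either region after adjustment, against 3 in striatum and 1 in prefrontal cortex at an unadjusted p under 0.05, and no other tool was run. Within non-neuronal nuclei the oligodendrocyte difference in striatum was -0.19 (adjusted p 0.686). Shares sum to 100%, so a fall of 1 class raises the others.

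**Figure D4:**
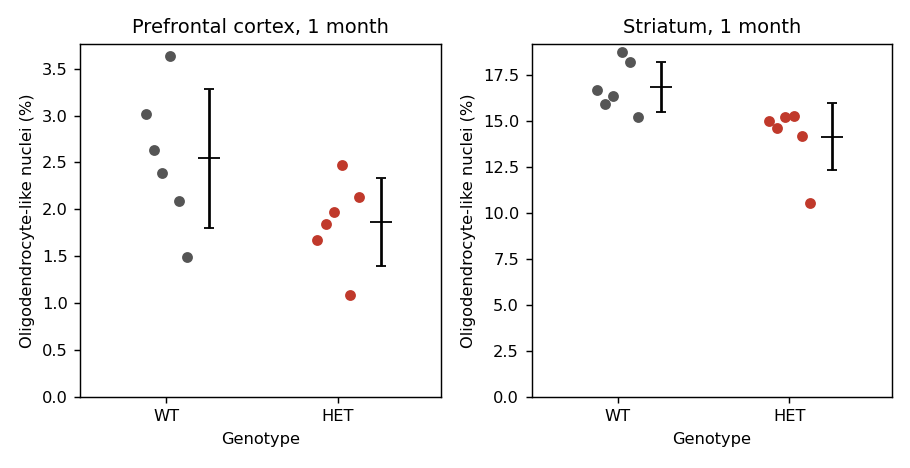
Oligodendrocyte share of nuclei in percent (vertical axis) in each library by genotype (horizontal axis), in prefrontal cortex (left) and striatum (right), with mean and SD. Striatal means were 16.9% in WT and 14.2% in HET.

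Of the preset lists, 8 process lists were tested in nuclei, and camera called 6 of 73 tests in prefrontal cortex (1 higher, 5 lower) and 24 of 81 in striatum (5 higher, 19 lower). With an estimated correlation camera called 0 tests in either region (smallest adjusted p 0.991 and 0.823), and 89 of 100 splits in prefrontal cortex and 28 of 100 in striatum gave as many calls with the preset correlation, so the number of calls is not beyond chance. Oxidative phosphorylation genes were lower in 4 classes of prefrontal cortex and in 5 of striatum, and higher in 1 of striatum. Cytosolic ribosomal protein genes were lower in 1 class of prefrontal cortex and 8 of striatum. Cholesterol biosynthesis genes were higher in 1 class of prefrontal cortex and lower in 3 of striatum. In striatum, immediate-early response genes were lower in 3 and higher in 1, while exome-wide schizophrenia risk, postsynaptic density and presynaptic release genes were each higher in 1 class. Splicing factor and nuclear speckle genes were called by camera in no class of either region. Members of these lists were called by edgeR over all genes 0 times in prefrontal cortex (1 adjusted over the list alone) and 2 times in striatum (7 adjusted over the list alone).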

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

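Tests chosen only after the result was seen were the correction for GC content and length, the tests on cortical markers in striatum, the comparison of 1-month bulk differences with nuclei, the tests on the oligodendrocyte share, the test of the cerebellum against the other regions and the counts over other splits of the samples. The tests of pseudogenes, of genes near Srrm2, of overlapping genes and of the genes shared by the ages in nuclei were set before their results were seen.

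In 15 of 112 groups of libraries, 1 library lay far from the others of its group, where chance alone gives about 1 in 20 groups (5.6 here). Srrm2 was at 231 CPM in HET 4 of 1-month hippocampus (other HET libraries 309 to 325), at 327 in HET 5 of 3-month somatosensory cortex (363 to 375), at 149 in HET 3 of 3-month hippocampus (333 to 402) and at 268 in HET 2 of 3-month striatum (352 to 379). It was at 690 CPM in WT 5 of 3-month cerebellar cortex (395 to 479), and without that library the log2 difference there was -0.06 against -0.21. Total counts stood apart in WT 3 of 1-month cerebellar cortex (55481655), WT 2 of 1-month hippocampus (50542141), HET 1 of 1-month somatosensory cortex (60018366), WT 1 of 3-month hippocampus (94142524) and WT 3 of 3-month somatosensory cortex (63654191), each above its group. Vascular fibroblasts made up 1.51% of nuclei in prefrontal WT 4 (others 4.80% to 5.57%). In striatal HET 6, oligodendrocytes made up 10.5% (others 14.2% to 15.3%), interneurons 4.10% (2.09% to 2.80%) and neural progenitors or neuroblasts 2.31% (0 to 0.608%). Eccentric projection neurons made up 2.57% in striatal WT 5 (1.83% to 2.07%). The causes were not tested.

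Differences between HET and WT depended on age in 725 genes of the mean over 6 regions, and in 17 genes in somatosensory cortex, 109 in striatum, 1 in thalamus, 195 in substantia nigra, 13 in cerebellar cortex and 4 in cerebellar vermis, each by a test of the interaction. An effect of age is not separated there from any difference in handling or processing of the 1-month HET libraries, since the labels give no batch. The fall of Srrm2 was smaller in the cerebellum than in the 6 other regions by 0.50 on the log2 scale at 1 month, and than in 4 others by 0.48 at 3 months. Its cause was not tested.

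For the 6271 genes changed at 1 month in the mean over regions, GC content and length, as far as the correction models them, were excluded as the whole cause. Of the 6271, 1778 were still called in the same direction after both had been corrected for. In all 2583 genes were called with the correction: besides the 1778, 714 were not called without it, and the others were called in opposite directions. The median size of the differences of the 6271 genes fell from 0.173 to 0.0806, and Spearman's rho with GC content across genes went from -0.621 to -0.0161. Less cortical tissue in the striatal samples of HET was excluded as the whole cause, since 6014 genes were called with striatum left out. A candidate explanation for part of the rest is that reads shared between near-identical copies were assigned differently in the 1-month HET libraries: the 300 processed pseudogenes had a median size of 0.242 against 0.119 in coding genes of like expression, a ratio of 2.04. That was the highest of 126 splits, but by a small margin, as the next also rounded to 2.04, and with the correction 7 of 126 splits reached the ratio of 1.65; at 3 months 18 of 126 splits reached the real ratio, 1.43, without the correction, and 39 of 126 reached the real ratio with it. In striatum 62.6% of the called genes (1806 of 2886) had the same sign in nuclei, which 15 of 924 assignments of the libraries reached (highest other 66.5%), but the share was 60.1% with the correction (reached by 0.0649 of assignments) and 58.3% among the 561 genes that less cortical tissue would move the other way (reached by 74 of 924), so striatum does not decide; in prefrontal cortex the share was 52.0% (447 of 859), which 398 of 924 assignments reached (highest other 74.9%), and with the correction 70.8% (17 of 24), which 125 of 924 reached, so prefrontal cortex does not either. Genotype at 1 month and any difference in handling or processing of the 1-month HET libraries stay open together, since the labels give no batch.

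The lower share of oligodendrocytes among HET nuclei was weighed next. Doublet removal and cluster resolution were excluded, since the difference kept at least 0.985 of its size under either alternative, and so was a loss in the filters on nuclei as the whole cause. Of the nuclei that failed them, 62 of 318 in WT and 63 of 354 in HET held a UMI of a preset oligodendrocyte marker in prefrontal cortex, and 406 of 1473 and 414 of 1815 in striatum, and counting these as oligodendrocytes left 0.941 and 0.933 of the difference in log2 odds (0.781 and 0.671 if counted in HET alone), while a loss before the deposited barcodes was not tested. Kept prefrontal oligodendrocytes had more UMIs in HET (mean of library medians 2386 ± 281 against 2015 ± 254 in WT, SD, n = 6 each, exact permutation p 0.0325). In striatum they had 3338 ± 620 against 3672 ± 412 (p 0.299 by the same test). Those of prefrontal cortex with under 1000 genes numbered 12 to 112 per WT library and 11 to 53 per HET library. Fewer oligodendrocytes in the tissue cannot be told apart from a lower yield of their nuclei. The myelinating list in 1-month bulk prefrontal cortex had a median of -0.17 (exact permutation p 0.389, n = 5 each), against -0.45 for the log2 ratio of the shares. In bulk striatum its median was 0.0276 (p 0.690 by the same exact test), against -0.25, and 9 of 27 list genes were lower in HET bulk tissue. The same HET samples of striatum had lower cortical markers. The list's mean level in WT was lower in somatosensory cortex (5.46 log2 CPM) than in striatum (7.35), so a difference in the dissected tissue is not separated there.

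The 74 genes called in the same direction at both ages were weighed last. GC content and length were excluded as the whole cause, since 40 genes were called at both ages after the correction, 33 of them among the 74. Alleles linked to the mutated locus were excluded as the cause for most of them. Of the 74, 2 genes, Mettl26 and Haghl, lay within 10 Mb of Srrm2 (2.70% against 1.89% of the other genes, Fisher's exact p 0.652). For those 2 genes linkage stays open. It also stays open for genes farther along chromosome 17, such as Ring1 (start 34020792) and Vars (start 35000987), since a wider window was not tested. Reads shared between overlapping genes could not be decided, with 40 of 74 overlapping another gene (54.1% against 49.6%, Fisher's exact p 0.485). In nuclei 72.3% (47 of 65) had the same sign in prefrontal cortex, which 76 of 924 assignments reached (highest other 83.1%), and 67.6% (46 of 68) in striatum, which 190 of 924 reached (highest other 79.4%), so an effect of the mutation in both tissues and nuclei stays open as a hypothesis and chance is not excluded there.

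Whether chance can be excluded was asked by regrouping the same libraries. Each share was taken alone, without adjustment over the comparisons. At 1 month it was excluded in prefrontal cortex (1 of 30 splits as large; 938 against at most 1 in the others), somatosensory cortex (1 of 30; 300 against 1), striatum (1 of 30; 3060 against 1), thalamus (1 of 30; 472 against 11), substantia nigra (1 of 30; 2966 against 1), cerebellar cortex (1 of 30; 2038 against 1) and cerebellar vermis (1 of 30; 144 against 0). At 3 months it was excluded in substantia nigra (1 of 35; 193 against 1) and cerebellar cortex (1 of 30; 9 against 0). It was not excluded in 1-month hippocampus (7 of 30; 1 against 102), nor at 3 months in prefrontal cortex (2 of 30; 16 against 56), somatosensory cortex (2 of 30; 5 against 954), thalamus (2 of 30; 1 against 17) and cerebellar vermis (4 of 30; 1 against 29). With 0 genes called by edgeR in 3-month hippocampus and striatum (768 and 1255 at an unadjusted p under 0.05, 15 and 31 by DESeq2), all 30 of 30 splits were as large (highest other 1 and 1064). Where chance was excluded, regrouping does not separate genotype from a GC trend or a difference in handling shared by the HET libraries. With the GC and length correction edgeR called 0 genes in 3-month substantia nigra, 31 in 1-month prefrontal cortex and 243 in 1-month substantia nigra. In 1-month striatum the exclusion of chance leaves the dissection open beside genotype, since the mean of the cortical excitatory neuron markers was 6.48 ± 0.17 log2 CPM in WT and 5.38 ± 0.71 in HET (SD, n = 5 each, exact permutation p 0.00794), without overlap, and 10 genes were called with this mean as a covariate. Splits that called far more genes than the real one, as with 954, 1064 and 102, point to a structure of the samples other than genotype. In 3-month striatum the mean of the cortical excitatory neuron markers ranged from 3.57 to 6.36 log2 CPM in WT and from 2.09 to 6.62 in HET. Whether this spread gave the 1064 calls was not tested. Chance was excluded for the mean over regions at 1 month (1 of 100; 6271 against 2, and with the correction 2583 against 2) and at 3 months (1 of 100; 91 against 17, and with the correction 55 against 22).

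For the dependence on age in the mean over 6 regions, 2 of 100 splits were as large (725 against 1279 in the other), which points again to a structure of the samples. These splits regrouped the libraries within each age, which also breaks up any genotype difference common to both ages. They therefore ask whether genotype mattered at either age, and cannot exclude chance for the dependence on age. By region, the real split gave the most calls in somatosensory cortex (1 of 25, 17 against 5), striatum (1 of 25, 109 against 66), substantia nigra (1 of 25, 195 against 0) and cerebellar cortex (1 of 25, 13 against 1). Each of these shares, taken alone, is under 0.05, but for the reason given it does not exclude chance for the dependence on age. In addition, 1 of 25 is the smallest share possible, and the regions were tested without adjustment. In cerebellar vermis (1 of 25, 4 against 3) the margin was a single gene, which decides little. In thalamus 1 of 25 splits was as large (1 against 0), but a count of 1 was also reached by other splits in prefrontal cortex and cerebellar cortex, so a single gene decides little there. With 0 genes called by edgeR in prefrontal cortex and hippocampus (584 and 880 at an unadjusted p under 0.05, and 0 in both with RLE factors), all 25 of 25 splits were as large (highest other 1 and 0). Chance was not excluded for the number of list calls in bulk tissue (100 of 100; 80 against 132) or in nuclei of prefrontal cortex (89 of 100; 6 against 35) and striatum (28 of 100; 24 against 40), nor for the number of genes called in nuclei of prefrontal cortex (2 of 30; 24 against 73) and striatum (2 of 30; 15 against 21).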

How the results depend on the processing

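Alternatives chosen after the data were seen were the GC and length correction, alone or with the replicate block, the 1-month means over 6 regions and over 7 regions without striatum, the cortical markers as a covariate in 1-month striatum, and the alternatives for the cerebellar comparison of Srrm2 and for Srrm2 in nuclei. For counts over 1.5 times larger or smaller than reported, and for the reversed values, the cause was not tested, except where fewer or more genes or regions entered the test. With the correction, edgeR counts at 1 month were 31 in prefrontal cortex, 179 in somatosensory cortex, 0 in hippocampus, 96 in thalamus, 243 in substantia nigra, 485 in cerebellar cortex and 18 in cerebellar vermis. At 3 months they were 5 in prefrontal cortex, 2 in somatosensory cortex, 2 in thalamus, 0 in substantia nigra and 11 in cerebellar vermis. limma then called 2583 genes in the 1-month mean, 55 in the 3-month mean and 420 for the dependence on age, and Tmx3 reversed to -0.0081 in the 1-month mean, with and without the block. With DESeq2 the 1-month counts were 2102 in prefrontal cortex, 721 in somatosensory cortex, 187 in hippocampus, 1174 in thalamus, 3641 in cerebellar cortex and 1724 in cerebellar vermis. At 3 months they were 462 in prefrontal cortex, 100 in somatosensory cortex, 15 in hippocampus, 31 in striatum, 99 in thalamus, 1674 in substantia nigra, 230 in cerebellar cortex and 74 in cerebellar vermis. DESeq2 called Srrm2 in 12 bulk comparisons, and 75 genes in nuclei of prefrontal cortex and 65 of striatum. On simulated counts DESeq2 also called more unchanged genes than edgeR. With the replicate number as a block, 1-month counts were 357 in prefrontal cortex, 0 in hippocampus, 1017 in substantia nigra, 140 in cerebellar cortex and 8 in cerebellar vermis. At 3 months they were 6 in prefrontal cortex, 0 in somatosensory cortex, 0 in thalamus, 317 in substantia nigra (186 higher, 131 lower), 0 in cerebellar cortex, 0 in cerebellar vermis and 4 in the mean, with 49 genes in striatal nuclei and 10 lists in prefrontal nuclei. The block fits kept only replicate numbers found in both genotypes. By the numbers of the sample descriptions these were 4 in 3-month prefrontal cortex and 2 in 3-month substantia nigra. The block with the correction gave 1932 and 3 in the means at 1 and 3 months. Replicate numbers do not pair the bulk samples, as 0 of 16 comparisons had every same-numbered pair correlated above 0.1, and 18 of 76 pairs were, while libraries of nuclei were not checked for this. The unadjusted and DESeq2 counts beside each 0 by edgeR are those of the report. Without the low-count filter the counts were 4 in 1-month hippocampus, and at 3 months 26 in prefrontal cortex, 2 in thalamus, 449 in substantia nigra and 57 in the mean, with 463 for the dependence on age, 83 in nuclei of prefrontal cortex and 327 of striatum. The cortical markers as a covariate gave 10 in 1-month striatum. RLE factors gave 113 in 3-month substantia nigra. The mean over 6 regions gave 4088 at 1 month and that over all 8 regions gave 848 at 3 months. With an estimated correlation 0 lists were called by camera in bulk (80 with the preset correlation), 0 in prefrontal nuclei (6) and 0 in striatal nuclei (24). Within neurons, the share of D1 projection neurons reversed to -0.014 (0.14 over all nuclei, neither past the threshold).

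Leaving out 1 library at a time gave, at 1 month, 216 to 1028 genes in prefrontal cortex, 120 to 336 in somatosensory cortex, 0 to 8 in hippocampus, 2083 to 3186 in striatum, 215 to 504 in thalamus, 1550 to 3136 in substantia nigra, 422 to 2286 in cerebellar cortex and 2 to 604 in cerebellar vermis. At 3 months it gave 5 to 117 in prefrontal cortex, 0 to 7 in somatosensory cortex, 0 to 0 in hippocampus and striatum, 0 to 31 in thalamus, 0 to 415 in substantia nigra, 2 to 36 in cerebellar cortex and 0 to 34 in cerebellar vermis. The mean over regions gave 5147 to 6160 at 1 month and 26 to 363 at 3 months, the dependence on age 454 to 1375, the bulk lists 69 to 93 calls and Srrm2 6 to 9 called comparisons. At 3 months several of the highest counts came without HET 5. Among single genes, lists and shares in bulk, 592 values kept direction and side of the threshold under the other settings, 78 fell short of it, 8 came past it, 5 counts moved and 2 reversed. With 1 bulk library left out these numbers were 1132, 143, 5, 10 and 0. In nuclei 293 values kept both, 11 fell short, 37 moved and 1 reversed. The fall of Srrm2 kept its sign in each bulk comparison and nuclear class under each alternative run. Recovery of changed genes was partial: on simulated counts edgeR recovered 61.5% of genes changed 1.5-fold in 1-month prefrontal cortex and 20% in 3-month substantia nigra, which has the fewest libraries, and 10.9% in striatal oligodendrocyte nuclei.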

Other observations

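Pxn, lower in prefrontal cortex at 3 months and in prefrontal excitatory neurons at 1 month, was at 5.49 ± 0.16 log2 CPM in WT and 5.16 ± 0.13 in HET at 1 month (mean over 6 regions, SD, n = 5 each), and at 5.44 ± 0.17 and 5.07 ± 0.08 at 3 months. Ap1g2, higher in the same neurons, was at 2.34 ± 0.11 and 2.88 ± 0.27 at 1 month, and at 2.13 ± 0.27 and 2.66 ± 0.14 at 3 months. These 6 regions do not include prefrontal cortex or substantia nigra. Both genes were looked up in bulk tissue after their values in nuclei were seen. Genes without a count in each library of 1 age and genotype, with a mean above 0.1 CPM in each of the other 3 groups, were also counted after the fact. In 1-month HET there were 3, Apoo-ps, Gm37371 and Gm49496, and 0 in each of the other groups, a plain count with no test or other tool. Apoo-ps had 2013 counts over the 40 WT libraries of 1 month, 4204 over the 38 WT and 5764 over the 38 HET libraries of 3 months.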
